A study of Homo sapiens with 3 samples.

How the data were processed

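Nuclei were isolated from 3 frozen tumors by lysis, Dounce homogenization and filtering, and libraries were made with the 10x Genomics single cell 3' kit, per the labels' protocols. The labels give a target of 5000 nuclei for each tumor, and the deposited files hold 4836, 5144 and 7071 barcodes. Each library was deposited as a matrix of raw UMI counts per gene and nucleus, made with Cell Ranger 5.0.1 per the file headers and aligned to GRCh38 per the submitters' processing notes. The deposited counts are whole numbers, not normalized, with no barcode under 500 UMIs. The annotation release, the barcode-calling settings and whether intronic or antisense reads were counted are not given in the sources used here. Gene IDs and symbols were taken from the files (36601 genes), and coordinates from GENCODE 29 on GRCh38, in which 34616 of the IDs were found. Among the genes with levels printed in the report, IGF2, HMGA2, RNF43, ALDH1A2, GATA3, HOXC4, HOXB8, HOXB9 and HOXC9 overlap another annotated gene on the same strand. Others, such as WT1, MYCN and MEG8, overlap a gene on the opposite strand. Where counting did not use strand, those levels include the partner.

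Everything after the count matrices was computed here. The 3 libraries were compared over genes before use and differed far beyond sampling noise (chi-square per degree of freedom 300, 163 and 277 for the 3 pairs). None was therefore a copy of another, and each was counted as its own replicate. This check cannot show that the libraries came from separate donors, which the labels do not state. Nuclei with more than 5% mitochondrial UMIs were removed (57, 0 and 0), and the median mitochondrial share was 0.503%, 0.0920% and 0.121%. Scrublet, as implemented in scanpy 1.11.5 with an expected rate of 6%, called 0 doublets in each library and was therefore taken not to have worked. In its place, the nuclei with the highest Scrublet scores were removed at 0.8% per 1000 nuclei (183, 212 and 400 nuclei). This left 4596, 4932 and 6671 nuclei, 16199 in all.

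Each tumor was clustered on its own, with no integration across tumors. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were selected, scaled and limited to 10, and 30 principal components were taken. A shared-neighbour graph of 15 neighbours was divided with the Leiden algorithm at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0). All 18 gene lists tested later (528 genes) and 116 genes that were never analysed (XIST, TSIX, Y-linked and mitochondrial genes) were kept out of the variable genes. The 67 clusters were scored on 17 marker lists fixed before the data were examined, as the mean over a list's markers of log2(CPM + 5) minus the median over clusters. A cluster took the name of its best list if the score was at least 0.75, at least 3 markers reached 20 CPM, and its top 10 genes by fold held no more markers of another class than of its own. The top genes were ranked against nuclei of the same tumor in clusters with another best list. A cluster whose median UMI count was under 1/3 of its tumor's needed an own marker among the top 10 and a score 1 above the next list. This named 62 clusters and left 5 unnamed.

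The markers were fixed in advance, but the naming rule was not. It is the fourth version, chosen after the clusters were seen, and class shares and counts of nuclei with a MKI67 or TOP2A UMI had been seen under the third. No gene or list test had been seen under an earlier version, and the rule was not changed once they had. The third version was then run as an alternative. Unnamed nuclei include 346 of tumor 1 with a stromal marker score that were left out because CRYM, a blastema marker, was among their top genes. A cluster of 195 nuclei in tumor 3 with a blastema score of 1.06 was named epithelium-like (score 2.28). In tumor 2, clusters of 466 and 51 blastema-like nuclei were led by mitotic genes, and HSPA1A was among the top genes of a cluster of 281.

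For comparisons between classes, raw UMI counts were summed per tumor and class, for classes with at least 30 nuclei in a tumor. Stroma-like sums held 2206, 728 and 2847 nuclei, epithelium-like sums 856, 89 and 1788, and blastema-like sums 131 and 2920 (tumors 1 and 2). The sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, glmQLFit and glmQLFTest, two-sided) with the tumor as a block. The pairing comes from both sums being of the same tumor. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and the SE of a log2 fold change was taken from the test's F statistic. Genes used as clustering features in any tumor (4435) and the 149 marker genes were not tested, since the clusters had been made or named from them. CPM of named genes are scaled with the TMM factors. Only the classes of a comparison entered its fit. Leaving out 1 of 2 tumors leaves no residual degrees of freedom, so blastema-like comparisons have no such check.

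The 18 lists, fixed before the data were examined, were S phase, G2/M phase, Wilms tumor driver genes, imprinted genes, WNT target genes, IGF signalling and RNA-binding genes, retinoic acid genes, Notch genes, FGF and MAPK feedback genes, TGF-beta and BMP genes, hypoxia and glycolysis genes, extracellular matrix genes, HOX genes, renal developmental transcription factors, microRNA processing genes, cell-surface target genes, neuronal adhesion and axon guidance genes, and immediate early and heat shock genes. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over 54 tests, of which 18 passed. With an estimated correlation 0 of the 54 passed. That form of camera takes its p-value from the few residual degrees of freedom of the fit, and the preset form from the number of genes. For HOX genes between epithelium-like and blastema-like nuclei the estimated correlation was -0.0299, below the preset one. Camera's p was still 0.0865 with it, against 1.22e-10 at the preset. Failing with an estimated correlation therefore does not by itself show that a call was owed to correlated members. In the same comparison the estimated correlation was 0.778 for G2/M phase and 0.244 for S phase, far above the preset one. For those lists correlated members may account for the small preset p, and this stays open.

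Nuclei with a MKI67 or TOP2A UMI were counted after each nucleus was thinned to 1500 UMIs, leaving out shallower nuclei. Classes were compared with a two-sided exact sign-flip test over tumors, adjusted over the 3 pairs of classes. Shares carry exact (Clopper-Pearson) 95% confidence intervals.

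Genes to be named were fixed by rule before the data were examined: WT1, IGF2, H19, CTNNB1, MYCN, LIN28B, HMGA2, MKI67, TOP2A, PAX2 and GPC3 always, then up to the 2 largest rises and 2 largest falls of each list among members past the threshold and of the same sign in every tumor, then the 10 largest rises and falls over all genes at a mean of at least 20 CPM. After the values were seen this was narrowed to the always-named genes and the single largest rise and fall of each list, to keep near 30 genes per comparison. The levels of some of those are not printed, and several of these genes lost the call in more alternatives than most printed genes. GRHL2 and ESRP1, among the 10 largest falls between stroma-like and blastema-like nuclei, were kept after their values were seen. The comparison of skeletal muscle-like with stroma-like nuclei in the closing section was chosen after the clusters were seen.

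The gene test was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. Each gene was drawn on its own from a negative binomial at edgeR's trended dispersion, with the same fold in every tumor. This is close to the model that the test fits, so few false calls were to be expected. They do not show how the test behaves where tumors differ in a change, or for classes made from the same data. For stroma-like against epithelium-like sums (14405 genes) it recovered 11% of genes changed 2-fold and 74% of those changed 4-fold, with 2 false calls among 87. For stroma-like against blastema-like sums (14118 genes) it recovered 7% and 58%, with 0 false calls among 65. For epithelium-like against blastema-like sums (12036 genes) it recovered 8% and 57%, with 1 false call among 66. For skeletal muscle-like against stroma-like sums (12508 genes) it recovered 21% and 83%, with 3 false calls among 107.

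Alternatives set before the data were examined were DESeq2 1.42.0, relative log expression size factors, no filter on low counts, each tumor left out, no block, doublets kept, Leiden resolutions of 0.5 and 2, at least 1000 UMIs per nucleus, sums thinned to the same total, clustering features included, clustering on a random part of the genes, an estimated correlation, limma's fry, and, for the share of nuclei with a MKI67 or TOP2A UMI, no thinning, thinning to 1000 or 3000 UMIs, and a UMI of at least 2 distinct G2/M genes. The earlier naming rule, and counting the cluster with the highest blastema score of each tumor as blastema-like, were added after the data were seen. Other tools were Python 3.11.15, anndata 0.12.19, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No copy number or sequence variant was inferred, and XIST and Y-linked genes were not analysed.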

Results

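Single-nucleus RNA sequencing was carried out on 3 frozen human Wilms tumors, childhood kidney cancers that can hold undifferentiated blastema, stroma and epithelium side by side. The tumors formed 1 group with 1 library each and no treatment or normal kidney, so populations of nuclei were compared within tumors. The libraries held 4836, 5144 and 7071 nucleus barcodes in tumors 1, 2 and 3, with totals of 23165948, 34775990 and 40185707 unique molecular identifiers (UMIs). The median UMI count per nucleus was 3800.5, 6428 and 4635, and the median number of detected genes was 1917, 2940 and 2382. After filtering, 4596, 4932 and 6671 nuclei were used. The labels do not say that the libraries came from separate donors, so differences between these samples may be technical in part. With the tumor as a block, gene p-values set a class difference within these tumors against its spread, which edgeR estimates partly from other genes. A gene can therefore pass though its change differs in size between tumors. List p-values at the preset correlation set the members of a list against the other genes, and do not measure the spread between tumors. Class names come from clusters rebuilt here and scored on fixed markers, and are written with "-like" for that reason.

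The tumors differed widely in composition. Blastema-like nuclei, named from markers of the nephron progenitor such as SIX2 and CITED1, made up 59.2% of tumor 2 (exact binomial 95% confidence interval 57.8 to 60.6%) and 2.85% of tumor 1 (2.39 to 3.37%). The tumor 1 share was 0% at Leiden resolutions of 0.5 and 2 and with at least 1000 UMIs per nucleus. The tumor 2 share was 69.3% with at least 1000 UMIs per nucleus, and 41.9% under an earlier naming rule, run after the data were seen. No cluster among the 6671 nuclei of tumor 3 was named blastema-like. Names were given to whole clusters, so this sets no upper limit on the share of such nuclei. A cluster of 195 nuclei there had a blastema score of 1.06 and was named epithelium-like (score 2.28). Stroma-like nuclei, named from collagen and other matrix markers, took 48.0% of tumor 1 (46.5 to 49.5%), 14.8% of tumor 2 (13.8 to 15.8%) and 42.7% of tumor 3 (41.5 to 43.9%). Epithelium-like nuclei, named from PAX8, LHX1, CDH1 and related markers, took 18.6% (17.5 to 19.8%), 1.80% (1.45 to 2.22%) and 26.8% (25.7 to 27.9%). Skeletal muscle-like nuclei were found in every tumor, at 8.99% (8.17 to 9.85%), 1.22% (0.930 to 1.56%) and 9.40% (8.71 to 10.1%). Over the 3 tumors the shares were 35.1% ± 17.9 (SD, n = 3) for stroma-like, 20.7% ± 33.4 for blastema-like, 15.7% ± 12.7 for epithelium-like and 6.53% ± 4.61 for skeletal muscle-like nuclei.

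Smaller populations were vascular and immune. Endothelium-like nuclei took 1.72%, 0.568% and 4.98% of tumors 1, 2 and 3. Pericyte or smooth muscle-like nuclei took 3.11% of tumor 1 and 5.04% of tumor 3, and none were named in tumor 2. At a Leiden resolution of 2 they took 2.43% of tumor 2, where a cluster of 585 stroma-like nuclei had a pericyte score of 1.46 beside its stroma score of 1.79. Relative to their mean, macrophage-like nuclei were the steadiest of these classes, at 1.09%, 1.30% and 1.60% (mean 1.33% ± 0.260, SD, n = 3). T or NK-like nuclei took 0.479% of tumor 1 and 0.315% of tumor 3, and mast-like nuclei 0.240% of tumor 3. The T or NK-like share of tumor 3 was 0% and 0.794% at Leiden resolutions of 0.5 and 2, and that of tumor 2 was 0.172% with at least 1000 UMIs per nucleus. In tumor 2 the stroma-like share was 9.43% at a Leiden resolution of 2, and the epithelium-like share 3.02% with at least 1000 UMIs. Clusters without a name held 15.1%, 21.1% and 8.95% of nuclei, or 7.62%, 38.4% and 0.884% under the earlier naming rule. The unnamed cluster of tumor 2 (1043 nuclei) scored 1.85 for blastema, and that of tumor 3 (597 nuclei) 3.02 for epithelium. Both were left unnamed for a low UMI count without a clear marker profile. Epithelium-like nuclei took 35.8% of tumor 3 under the earlier rule, and stroma-like nuclei 59.9% of tumor 1 with at least 1000 UMIs. Intervals cover counting error only, and the share of a class also depends on how the nuclei were isolated and named. With 1 library per tumor, the tumors were described and not tested against each other.

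**Figure D1:**
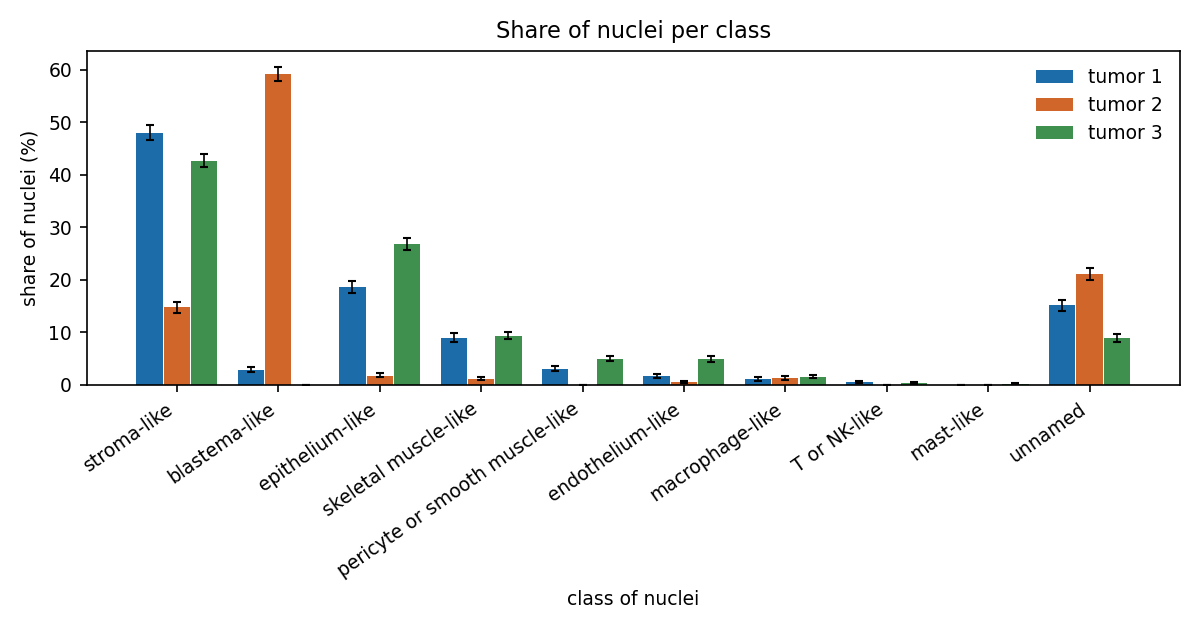
Share of nuclei (%) in each class, with 1 bar per tumor and exact binomial 95% confidence intervals. Blastema-like nuclei dominate tumor 2 (59.2%), and stroma-like nuclei are the most numerous class in tumors 1 and 3 (48.0% and 42.7%).

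The first comparison asked how stroma-like and epithelium-like nuclei of the same tumors differed, and all 3 tumors held both classes. PAX2, a transcription factor of the nephron lineage on chromosome 10 (GRCh38, 100735603 to 100829941), fell by 4.76 ± 0.34 (SE) on the log2 scale in stroma-like nuclei, from 975 ± 144 to 39.7 ± 20.9 CPM (UMI counts scaled to the library total; SD, n = 3; adjusted p = 0.00259). GATA3, a regulator of the collecting duct lineage (ENSG00000107485, chromosome 10, 8045378 to 8075203), was at 107 ± 35.2 CPM in epithelium-like and 3.52 ± 1.88 CPM in stroma-like nuclei (log2 fold change -4.90 ± 0.32, adjusted p = 0.00249). On the stromal side stood PDGFRB, the PDGF receptor of mesenchymal cells (chromosome 5, 150113837 to 150155872), at 193 ± 19.4 against 10.8 ± 5.55 CPM (log2 fold change 4.17 ± 0.31, adjusted p = 0.00272). COL12A1, a fibril-associated collagen, was at 254 ± 280 against 8.51 ± 6.84 CPM, and the transcription factor OSR2 at 51.6 ± 38.4 against 2.85 ± 1.79 CPM (log2 fold changes 4.76 ± 0.31 and 4.24 ± 0.23). Each of these genes moved the same way in 3 of 3 tumors.

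In total 2600 of 14801 tested genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1290 of them higher in stroma-like and 1310 higher in epithelium-like nuclei. Without tumor 3 the count was 769 and without tumor 1 it was 1085, and it was 480 when the tumor was not used as a block. Of the 31 called genes named for this comparison, 24 lost the call with no replicate block, 13 without tumor 3 and 12 without tumor 1, none with a change of sign. HMGA2 passed as lower in stroma-like nuclei, at 743 ± 396 against 1189 ± 461 CPM (-0.75 ± 0.18, adjusted p = 0.0417), and lost the call in 7 of 16 alternatives. MYCN lost it in 4 of 15, and each other called gene with a level printed for this comparison in 3 or fewer. Among called genes whose levels are not printed here, CCNB2 lost it in 11 of 16, and BLM, PRICKLE1 and RDH10 in 5 of 16.

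The extracellular matrix list shifted most. Of its 43 tested members, 26 were higher and 6 lower in stroma-like nuclei (28 and 6 adjusted over the list alone), with a median log2 fold change of 1.37 (camera, adjusted p = 5.9e-13, and adjusted p = 0.716 with an estimated correlation). The members lower in stroma-like nuclei included COL4A4, a basement membrane collagen, at 2.20 ± 1.61 against 44.6 ± 51.1 CPM (log2 fold change -4.15 ± 0.33, adjusted p = 0.00292). Stroma-like nuclei had been named from matrix markers, which were not tested themselves, so the direction of this list is not independent of the names. Neuronal adhesion and axon guidance genes rose as a list, with 8 of 30 members higher and 0 lower (9 and 0 adjusted over the list alone; median 0.81, adjusted p = 0.0126, adjusted p = 0.716 with an estimated correlation and 0.0996 without the tumor block). NTN1, a secreted guidance cue, was at 90.4 ± 62.2 against 12.8 ± 9.24 CPM (log2 fold change 2.82 ± 0.17, adjusted p = 0.00240).

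Imprinted genes were higher in stroma-like nuclei as a list, with 7 of 24 members higher and 2 lower (9 and 5 adjusted over the list alone; median 0.43, adjusted p = 0.00923, adjusted p = 0.716 with an estimated correlation and 0.103 without the tumor block). MEG8, a maternally expressed RNA (ENSG00000225746, chromosome 14, 100894770 to 101038859), was at 890 ± 553 against 121 ± 82.4 CPM (log2 fold change 2.93 ± 0.17, adjusted p = 0.00227). The growth factor IGF2 (ENSG00000167244, chromosome 11, 2129112 to 2149603) was at 18.9 ± 7.04 against 4.13 ± 2.31 CPM (log2 fold change 2.36 ± 0.27, adjusted p = 0.00613, higher in 3 of 3 tumors). IGF2 overlaps AC132217.1 and AC132217.2 on its own strand, so its level is uncertain. Its neighbour H19, a long non-coding RNA (chromosome 11, 1995176 to 2001470), was at 133 ± 116 against 48.2 ± 43.1 CPM (log2 fold change 1.27 ± 0.22, adjusted p = 0.0165), with only 2.25 and 1.51 CPM in tumor 3. KCNQ1, in contrast, was lower in stroma-like nuclei, at 47.3 ± 25.5 against 98.6 ± 51.2 CPM (log2 fold change -1.07 ± 0.15, adjusted p = 0.0105).

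TGF-beta and BMP genes rose as a list, with 9 of 31 members higher and 3 lower (10 and 3 adjusted over the list alone; median 0.20, adjusted p = 0.0233, and adjusted p = 0.716 with an estimated correlation). The BMP antagonist GREM1 was higher (log2 fold change 4.27 ± 0.31), and the receptor BMPR1B was lower, at 41.2 ± 18.8 against 295 ± 118 CPM (-2.86 ± 0.46, adjusted p = 0.0145). HOX genes fell as a list, with 12 of 31 members lower and 3 higher (13 and 7 adjusted over the list alone; median -0.41, adjusted p = 0.00923, and adjusted p = 0.716 with an estimated correlation). HOXB8 was at 4.14 ± 3.59 against 22.9 ± 14.6 CPM (-2.66 ± 0.32, adjusted p = 0.00655), while HOXC4 was at 37.6 ± 10.8 against 13.1 ± 7.33 CPM (1.67 ± 0.27, adjusted p = 0.0147). HOXB8 and HOXC4 each overlap other HOX genes on the same strand, so their own levels are uncertain. Without tumor 3 the adjusted p was 0.193 for the TGF-beta and BMP list and 0.242 for the HOX list, whose median became 0.03. Over all alternatives these p-values ran from 0.0168 to 0.193 and from 0.00749 to 0.242.

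Genes also differed in lists that did not pass as a whole. The fibroblast growth factor FGF7 was at 122 ± 57.7 CPM in stroma-like and 7.77 ± 3.66 CPM in epithelium-like nuclei (log2 fold change 4.26 ± 0.50, adjusted p = 0.00640). FGF20, a ligand of the nephron progenitor niche, lay on the other side, at 2.17 ± 2.13 against 54.9 ± 84.1 CPM (-3.88 ± 0.68, adjusted p = 0.0179). IGF1 was at 118 ± 103 against 8.29 ± 8.21 CPM (3.96 ± 0.25, adjusted p = 0.00249), and ALDH1A2, a retinoic acid-synthesizing enzyme, at 397 ± 129 against 85.8 ± 22.0 CPM (2.19 ± 0.24, adjusted p = 0.00530). The WNT feedback ligase RNF43 was at 37.8 ± 25.8 against 221 ± 104 CPM (-2.75 ± 0.55, adjusted p = 0.0262). The oncogene MYCN was at 3.68 ± 4.61 against 12.2 ± 7.10 CPM, and LIN28B, a repressor of let-7 microRNA processing, at 21.3 ± 31.9 against 71.8 ± 83.0 CPM (log2 fold changes -2.34 ± 0.47 and -2.49 ± 0.37, adjusted p = 0.0266 and 0.0114).

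Several genes tied to Wilms tumor did not pass the test between stroma-like and epithelium-like nuclei. WT1, the kidney transcription factor and tumor suppressor (chromosome 11, 32387775 to 32435630), had a log2 fold change of -1.65 ± 1.36 (adjusted p = 0.453), with a ratio below 1 in tumors 1 and 3 and above 1 in tumor 2. Values were -0.09 ± 0.20 for CTNNB1 (adjusted p = 0.802), 0.54 ± 0.81 for GPC3 (0.694), -0.05 ± 0.19 for MKI67 (0.905) and -0.18 ± 0.21 for TOP2A (0.596). Without tumor 2, WT1 passed as lower (-4.30, adjusted p = 0.00575) and GPC3 as higher in stroma-like nuclei (1.60, adjusted p = 0.00486). The lists that did not pass in this comparison had adjusted p = 0.0987 for retinoic acid genes, 0.105 for hypoxia and glycolysis genes, 0.315 for Wilms tumor driver genes and for G2/M phase, 0.334 for IGF signalling and RNA-binding genes and 0.401 for renal developmental transcription factors. They were 0.444 for WNT target genes, 0.461 for S phase, 0.578 for immediate early and heat shock genes, 0.644 for FGF and MAPK feedback genes, 0.645 for cell-surface target genes, and 0.896 for both Notch and microRNA processing genes. Without tumor 1 the lists of G2/M phase (median -0.27, adjusted p = 0.0410), WNT target and retinoic acid genes (medians 0.40 and 0.59, adjusted p = 0.0301 for both) passed, and without tumor 2 the hypoxia and glycolysis list did (median -0.47, adjusted p = 0.0370). The IGF signalling list had a median of -0.03 against a mean of 0.32, and the microRNA list a median of 0.02 against a mean of -0.08.

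**Figure D2:**
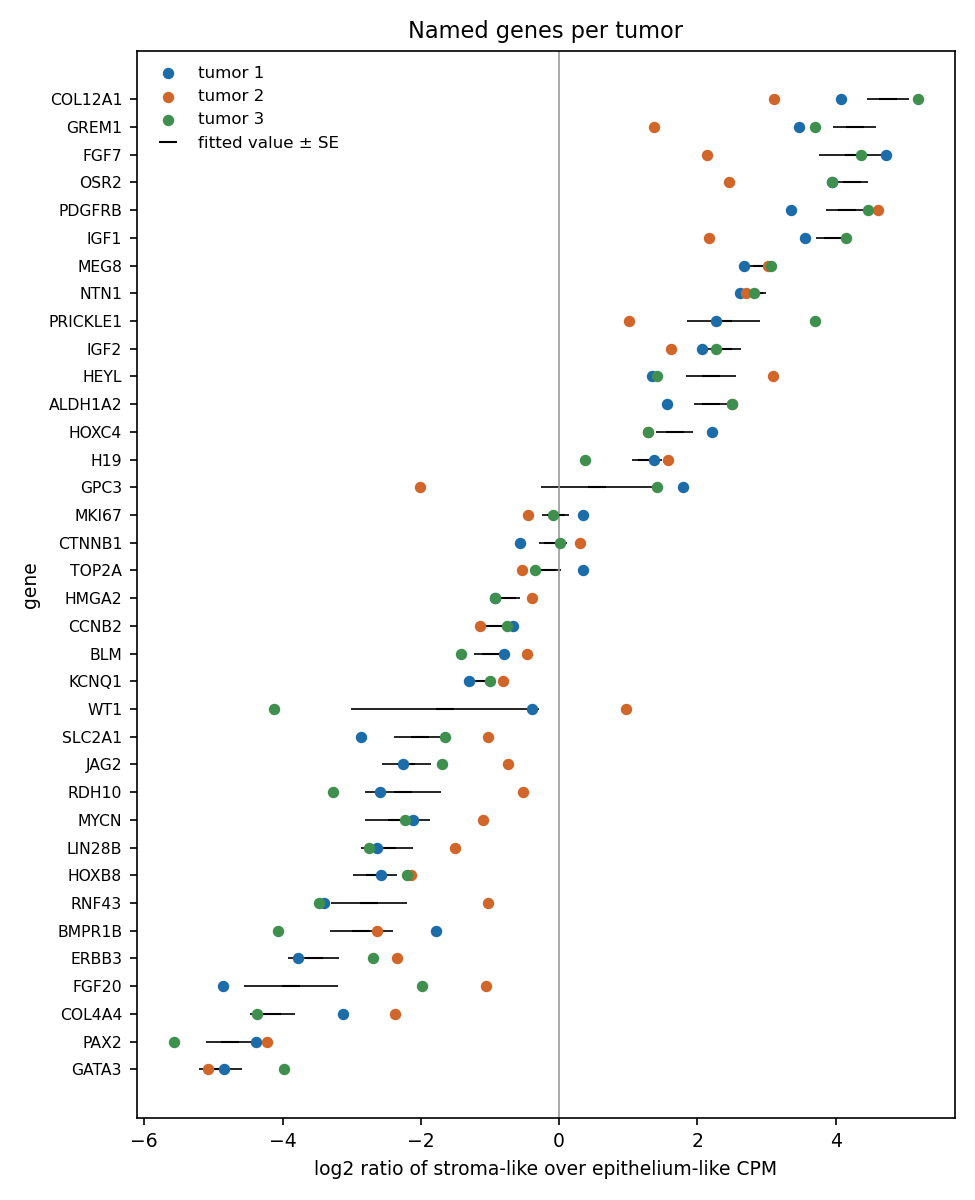
Log2 ratio of stroma-like over epithelium-like CPM for the named genes, with 1 point per tumor and the fitted value ± SE as a black mark. Points were computed with 1 CPM added to each level, which draws those of low-count genes toward 0. PAX2, GATA3 and PDGFRB lie on the same side of 0 in 3 of 3 tumors, while WT1 and GPC3 lie on both sides.

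The next comparison asked how stroma-like nuclei differed from blastema-like nuclei, which tumors 1 and 2 held. The proliferation genes CENPF, MKI67 and TOP2A were lower in stroma-like nuclei. CENPF, a kinetochore protein of G2 and mitosis, was at 108 ± 7.93 against 334 ± 26.7 CPM (SD, n = 2; log2 fold change -1.62 ± 0.25, adjusted p = 0.00196). MKI67 was at 57.1 ± 12.4 against 123 ± 23.7 CPM and TOP2A at 104 ± 16.0 against 239 ± 21.6 CPM (-1.11 ± 0.24 and -1.20 ± 0.24, adjusted p = 0.0110 and 0.00766). Other genes that fell were PAX2, at 50.3 ± 13.6 against 450 ± 273 CPM (-3.03 ± 0.40, adjusted p = 0.000792), MYCN, at 5.06 ± 5.51 against 23.4 ± 8.09 CPM (-2.47 ± 0.49, adjusted p = 0.00781), and LIN28B, at 30.9 ± 38.0 against 131 ± 28.9 CPM (-2.85 ± 0.59, adjusted p = 0.00934). The growth factor receptor EGFR rose from 4.61 ± 2.87 CPM in blastema-like to 77.5 ± 18.2 CPM in stroma-like nuclei (4.39 ± 0.34, adjusted p = 2.21e-05). Each of these genes moved the same way in 2 of 2 tumors.

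By the same edgeR test, 1486 of 14596 tested genes differed, 942 higher in stroma-like and 544 higher in blastema-like nuclei. The count was 854 with DESeq2, 745 with another scaling, 565 with the sums thinned to equal totals and 0 without the tumor block, where 1201 genes had an unadjusted p under 0.05. The fit rested on 1 residual degree of freedom, and tumor 1 contributed a single blastema-like cluster of 131 nuclei whose blastema score (1.47) was close to its epithelium score (1.41). That cluster carried the epithelial genes GRHL2 and ESRP1 at 273 and 98.4 CPM, against 1.64 and 3.90 CPM in the blastema-like nuclei of tumor 2 and 399 and 87.7 CPM in the epithelium-like nuclei of tumor 1. Both genes passed as lower in stroma-like nuclei (-3.89 and -3.33, adjusted p = 0.00390 and 0.0118). Of 9 alternatives, the call was lost in 7 for WT1, in 4 for LIN28B and COL2A1, in 3 for MYCN, LTBP1 and HOXB9, in 2 for MKI67 and CNTN5, and in 1 for each other always-named or list gene with a level printed as passing here. Among called list genes whose levels are not printed here, EGR1 lost it in 8, DLL1 in 7, ALDH1A1 in 6, and FZD7, FGF8 and SLC2A1 in 5.

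G2/M phase genes fell as a list, with the smallest p of the lists in this comparison. Of 52 members, 26 were lower and 0 higher in stroma-like nuclei (40 and 0 adjusted over the list alone; median -0.92, camera, adjusted p = 5.42e-20, and adjusted p = 0.716 with an estimated correlation). In S phase, 7 of 42 members were lower and 0 higher (10 and 0 adjusted over the list alone; median -0.63, adjusted p = 2.54e-08, and adjusted p = 0.716 with an estimated correlation). The helicase BLM was the S phase member with the largest fall, at 21.1 ± 2.78 against 63.1 ± 28.1 CPM (-1.50 ± 0.28, adjusted p = 0.00536). These cell cycle results depend on how clusters led by mitotic genes were named. In tumor 2 those of 466 and 51 nuclei were named blastema-like (scores 1.48 and 1.73, next scores 0.551 and 0.402), and no stroma-like cluster was so led. In tumor 1 such a cluster of 147 nuclei was named stroma-like. The effect of these names was not tested. HOX genes fell as a list, with 14 of 33 members lower and 0 higher (18 and 0 adjusted over the list alone; median -0.95, adjusted p = 1.67e-11, and adjusted p = 0.716 with an estimated correlation). HOXB9 was at 9.29 ± 8.72 against 40.0 ± 2.85 CPM (-2.32 ± 0.48, adjusted p = 0.00932).

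Wilms tumor driver genes were lower as a list in stroma-like nuclei, with 4 of 36 members lower and 0 higher (4 and 0 adjusted over the list alone; median -0.15, adjusted p = 0.00759, and adjusted p = 0.716 with an estimated correlation). WT1 was among them, at 139 against 315 CPM in tumor 2 but 0.23 against 1.11 CPM in tumor 1 (log2 fold change -1.23 ± 0.33, adjusted p = 0.0327). Renal developmental transcription factors moved in both directions, with 11 of 30 lower and 5 higher (14 and 7 adjusted over the list alone; median -0.72, adjusted p = 0.0388, and adjusted p = 0.716 with an estimated correlation). Over the alternatives that p ran from 0.0281 to 0.156, and it passed the threshold only without the tumor block. SIM1 was a member higher in stroma-like nuclei, at 224 against 2.21 CPM in tumor 1 and 3.51 against 0.31 CPM in tumor 2 (4.82 ± 0.53, adjusted p = 0.000213).

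Extracellular matrix genes rose against blastema-like nuclei as well, with 22 of 42 higher and 3 lower (29 and 3 adjusted over the list alone; median 1.28, adjusted p = 5e-16, and adjusted p = 0.716 with an estimated correlation). LAMA2, a laminin chain, was at 179 ± 152 against 12.8 ± 16.4 CPM (4.83 ± 0.48, adjusted p = 9.53e-05), while the cartilage collagen COL2A1 was lower, at 25.5 ± 33.1 against 122 ± 39.1 CPM (-3.16 ± 0.65, adjusted p = 0.00898). Imprinted genes rose as a list, with 4 of 23 higher and 0 lower (7 and 2 adjusted over the list alone; median 0.46, adjusted p = 0.0205, adjusted p = 0.716 with an estimated correlation and 0.0646 without the tumor block). MEG8 led them, at 742 ± 696 against 79.5 ± 84.6 CPM (3.41 ± 0.30, adjusted p = 5.08e-05), whereas IGF2 (0.86 ± 0.40, adjusted p = 0.239) and H19 (0.62 ± 0.24, adjusted p = 0.135) did not pass. In the TGF-beta and BMP list, 9 of 31 members were higher and 2 lower (12 and 5 adjusted over the list alone; median 0.40, adjusted p = 0.0426, and adjusted p = 0.716 with an estimated correlation). That list's p was 0.114 with the sums thinned and ran from 0.0163 to 0.114 over the alternatives. LTBP1, which binds latent TGF-beta, was lower in stroma-like nuclei, at 530 ± 61.6 against 1520 ± 762 CPM (-1.43 ± 0.35, adjusted p = 0.0224).

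Other called genes higher in stroma-like than in blastema-like nuclei were FGF7 (102 ± 66.9 against 5.58 ± 0.0663 CPM, log2 fold change 3.72 ± 0.35), IGFBP7 (3.13 ± 0.48) and the ephrin receptor EPHA3 (567 ± 495 against 21.8 ± 16.1 CPM, 4.56 ± 0.30). Called genes higher in blastema-like nuclei were the contactin CNTN5 (1359 ± 605 against 214 ± 12.2 CPM, -2.59 ± 0.34) and the retinol dehydrogenase RDH10 (160 ± 14.0 against 41.6 ± 19.4 CPM, -2.01 ± 0.30). HMGA2, abundant in both classes, was at 942 ± 272 against 1860 ± 16.7 CPM and did not pass (-1.01 ± 0.36, adjusted p = 0.108), though it passed in 2 of 9 alternatives (DESeq2, and the highest blastema score counted as blastema-like). Neither did CTNNB1 (0.28 ± 0.25, adjusted p = 0.612) or GPC3 (0.12 ± 0.38, adjusted p = 0.916) pass. Lists that did not pass had adjusted p = 0.0519 for retinoic acid genes, 0.0807 for hypoxia and glycolysis, 0.0979 for WNT targets, 0.0987 for cell-surface targets, 0.192 for neuronal adhesion, 0.578 for microRNA processing, 0.603 for immediate early and heat shock, 0.624 for Notch, 0.645 for IGF signalling and 0.963 for FGF and MAPK feedback genes. The FGF list had a median of -0.06 against a mean of 0.07.

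The last comparison set epithelium-like against blastema-like nuclei in tumors 1 and 2. The proliferation genes MKI67 and TOP2A were lower in epithelium-like nuclei. MKI67 was at 60.6 ± 12.6 against 128 ± 24.1 CPM and TOP2A at 125 ± 73.8 against 249 ± 23.7 CPM (SD, n = 2, log2 fold changes -1.09 ± 0.25 and -1.13 ± 0.26, edgeR adjusted p = 0.0291 and 0.0310). The axon guidance receptor DCC fell furthest among the named genes, at 354 ± 317 against 2682 ± 2507 CPM (-2.88 ± 0.21, adjusted p = 4.57e-05). WT1 was at 74.0 against 330 CPM in tumor 2 and at 0.61 against 1.15 CPM in tumor 1 (-2.08 ± 0.31, adjusted p = 0.00285), and H19 at 73.0 ± 19.3 against 136 ± 31.3 CPM (-0.90 ± 0.21, adjusted p = 0.0357). Of 9 alternatives, the call was lost in 6 for H19, in 5 for TOP2A and MAML2, in 4 for TACC3, in 3 for MKI67 and ERBB4, in 2 for WT1, LTBP1 and SIM1, and in 1 for each other gene with a level printed as passing here. Among called list genes whose levels are not printed here, TNFRSF19 and ETV1 lost it in 5, and HDAC4, IGF2BP1 and HSPA1A in 4. The retinaldehyde dehydrogenase ALDH1A1 rose, at 57.3 ± 58.8 against 3.70 ± 4.53 CPM (4.45 ± 0.42, adjusted p = 0.000223), as did the receptor ERBB4, at 110 ± 135 against 5.25 ± 0.714 CPM (3.10 ± 0.55, adjusted p = 0.00843). SIM1 was at 148 ± 146 against 1.31 ± 1.40 CPM, and its fitted fold depends on very few blastema-like counts. Each of these genes moved the same way in 2 of 2 tumors. For WT1 both levels of tumor 1 lay near the floor, so its direction there carries little weight.

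In all, 460 of 12505 tested genes differed, 330 higher in epithelium-like and 130 higher in blastema-like nuclei. The count was 198 with DESeq2, 765 without the filter on low counts, 193 with thinned sums, 165 with clustering features included and 0 without the tumor block, where 393 genes had an unadjusted p under 0.05. Tumor 2 contributed only 89 epithelium-like nuclei, a single cluster with a blastema score of 1.45 beside its epithelium score of 1.78. The blastema-like clusters of tumor 2 had blastema scores of 1.26 to 1.73. The blastema-like sum of tumor 1 was the cluster with epithelial genes described above.

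G2/M phase genes were lower in epithelium-like nuclei, with 9 of 52 lower and 0 higher (36 and 0 adjusted over the list alone; median -0.93, camera, adjusted p = 1.83e-24, and adjusted p = 0.716 with an estimated correlation). TACC3, a spindle protein, was at 20.8 ± 0.845 against 54.7 ± 23.5 CPM (-1.39 ± 0.30, adjusted p = 0.0228). The estimated correlation of the G2/M list was 0.778 here, so its preset p may owe much to correlated members. The blastema-like sum of tumor 2 again held the clusters led by mitotic genes. No epithelium-like cluster of tumors 1 and 2 was led by such genes. The S phase list shifted down with none of its 41 members called alone (0 higher and 0 lower, also adjusted over the list alone; median -0.52, adjusted p = 2.54e-08, and adjusted p = 0.716 with an estimated correlation). HOX genes fell as a list, with 10 of 30 lower and 0 higher (15 and 0 adjusted over the list alone; median -0.83, adjusted p = 1.1e-09, and adjusted p = 0.716 with an estimated correlation), and HOXC9 was at 6.87 ± 4.54 against 38.6 ± 30.2 CPM (-2.41 ± 0.36, adjusted p = 0.00297). HOXC9 overlaps HOXC6 on the same strand.

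Cell-surface target genes rose as a list, with 4 of 15 higher and 0 lower (5 and 0 adjusted over the list alone; median 0.27, adjusted p = 0.0110, and adjusted p = 0.716 with an estimated correlation). Renal developmental transcription factors had 5 of 28 members higher and 7 lower (7 and 15 adjusted over the list alone), with a median of -0.92, a mean of 0.02 and adjusted p = 0.0149 in the downward direction (adjusted p = 0.716 with an estimated correlation). Their p was 0.743 with thinned sums and ran from 0.00400 to 0.743 over the alternatives. Other named genes that passed were TGFBR3 (81.4 ± 5.40 against 23.9 ± 7.71 CPM, log2 fold change 1.75 ± 0.26), COL2A1 (21.0 ± 2.79 against 127 ± 41.3 CPM, -2.48 ± 0.28), LTBP1 (664 ± 346 against 1585 ± 789 CPM, -1.27 ± 0.20) and MAML2 (2106 ± 649 against 991 ± 40.2 CPM, 1.05 ± 0.22). PAX2 was at 1028 ± 226 against 469 ± 282 CPM and did not pass (1.26 ± 0.34, adjusted p = 0.0657), though it passed in 2 of 9 alternatives (no filter on low counts, doublets kept). IGF2 (adjusted p = 0.481), CTNNB1 (0.627), MYCN (0.354), LIN28B (0.367, passing without the filter on low counts), HMGA2 (0.460) and GPC3 (0.874) did not pass either.

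Lists that did not pass between epithelium-like and blastema-like nuclei had adjusted p = 0.0782 for extracellular matrix, 0.105 for Wilms tumor drivers, 0.145 for immediate early and heat shock genes, 0.348 for both microRNA processing and neuronal adhesion, 0.354 for both WNT targets and FGF feedback, and 0.401 for hypoxia and glycolysis. They were 0.461 for TGF-beta and BMP, 0.503 for IGF signalling, 0.624 for Notch, 0.793 for retinoic acid and 0.883 for imprinted genes. Imprinted genes had a median of 0.11 against a mean of -0.03, and retinoic acid genes a median of -0.07 against a mean of 0.24. The neuronal adhesion list had a median of 0.21 and a mean of 0.04, and its test pointed down.

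**Figure D3:**
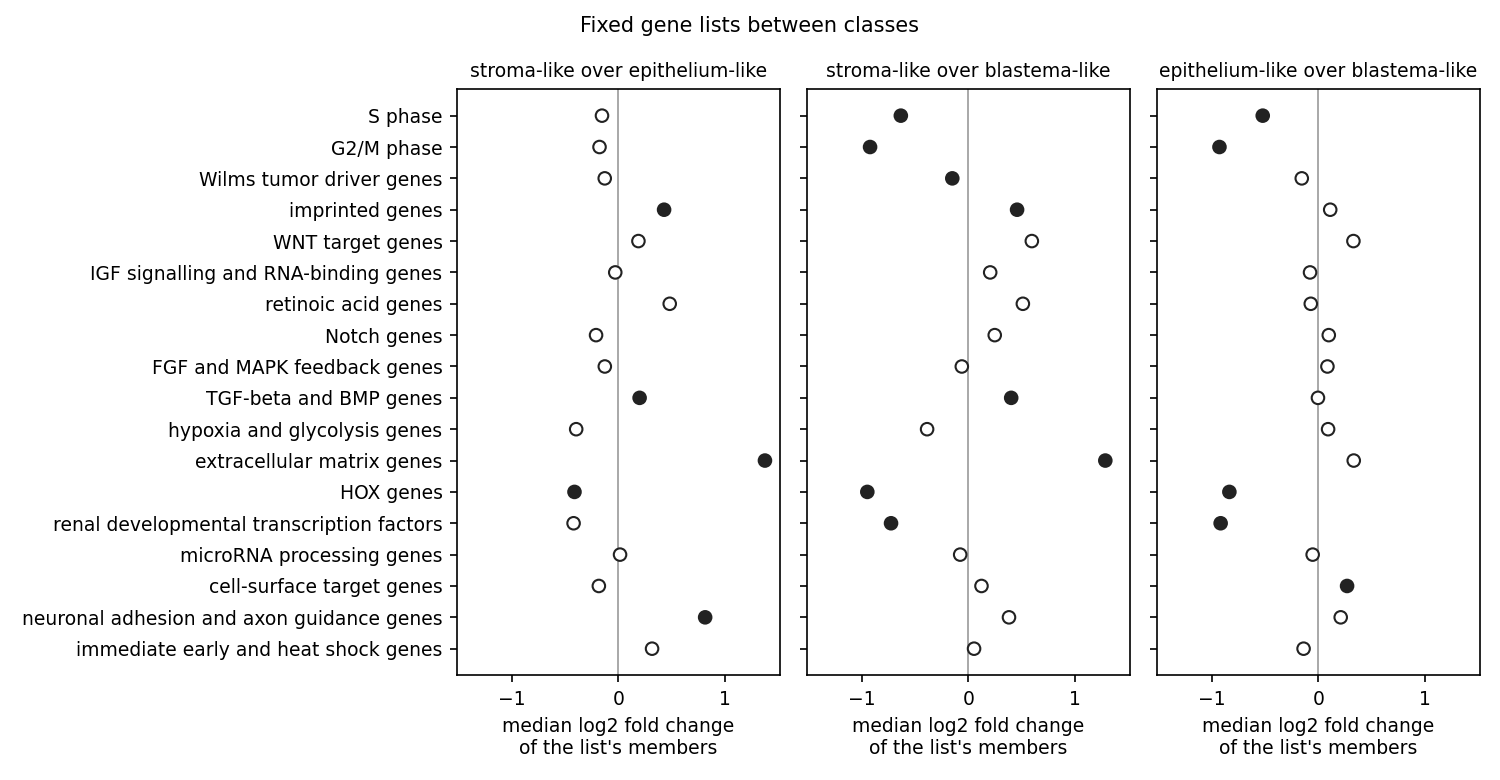
Median log2 fold change of the tested members of each fixed gene list in the 3 class comparisons, with filled points for camera's adjusted p under 0.05 at the preset correlation of 0.01. Matrix genes lie to the right in both stromal comparisons (1.37 and 1.28), and G2/M genes lie to the left against blastema-like nuclei (-0.92 and -0.93).

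Nuclei with a MKI67 or TOP2A UMI were also counted one by one, after each nucleus was thinned to 1500 UMIs. The share was 23.4% (exact binomial 95% confidence interval 16.4 to 31.7%) and 20.6% (19.1 to 22.1%) in the blastema-like nuclei of tumors 1 and 2. Blastema-like nuclei of tumor 2 include clusters of 466 and 51 nuclei led by mitotic genes. Stroma-like nuclei of tumors 1 and 3 include such clusters of 147 and 78 nuclei. The shares therefore depend on how these clusters were named. Epithelium-like nuclei were at 10.1%, 15.7% and 8.35% in tumors 1, 2 and 3, skeletal muscle-like nuclei at 8.17%, 13.6% and 7.98%, and stroma-like nuclei at 6.09%, 10.3% and 5.33%. Macrophage-like nuclei, taken as a level that free RNA in the droplets can reach, were at 6.67% (0.818 to 22.1%), 6.45% (1.79 to 15.7%) and 0% (0 of 97, interval up to 3.73%), and endothelium-like nuclei at 2.67% and 4.58% in tumors 1 and 3. The stroma-like and skeletal muscle-like shares of tumors 1 and 2 and the epithelium-like share of tumor 1 lay within the macrophage intervals of those tumors. Unthinned means were 41.8% for blastema-like, 25.0% for epithelium-like and 16.5% for stroma-like nuclei, and thinning left out 26, 100 and 445 shallower nuclei of these classes.

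Blastema-like exceeded stroma-like nuclei by 13.8 ± 5.03 percentage points (SD, n = 2, higher in 2 of 2 tumors; two-sided exact sign-flip p = 0.5, the smallest that 2 tumors allow), or by 8.68 with doublets kept and 22.3 with no thinning. They exceeded epithelium-like nuclei by 9.10 ± 6.02 points (n = 2, 2 of 2 tumors, exact p = 0.5), or by 4.84 in tumor 2 and 13.4 in tumor 1. Epithelium-like exceeded stroma-like nuclei by 4.13 ± 1.19 points (n = 3, 3 of 3 tumors, exact p = 0.25, the smallest that 3 tumors allow), and this difference was 1.38 points with doublets kept, 1.51 at 1000 UMIs and 8.47 with no thinning. None of the 3 differences could reach 0.05 in this design, and the Benjamini-Hochberg adjusted value was 0.5 for each.

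**Figure D4:**
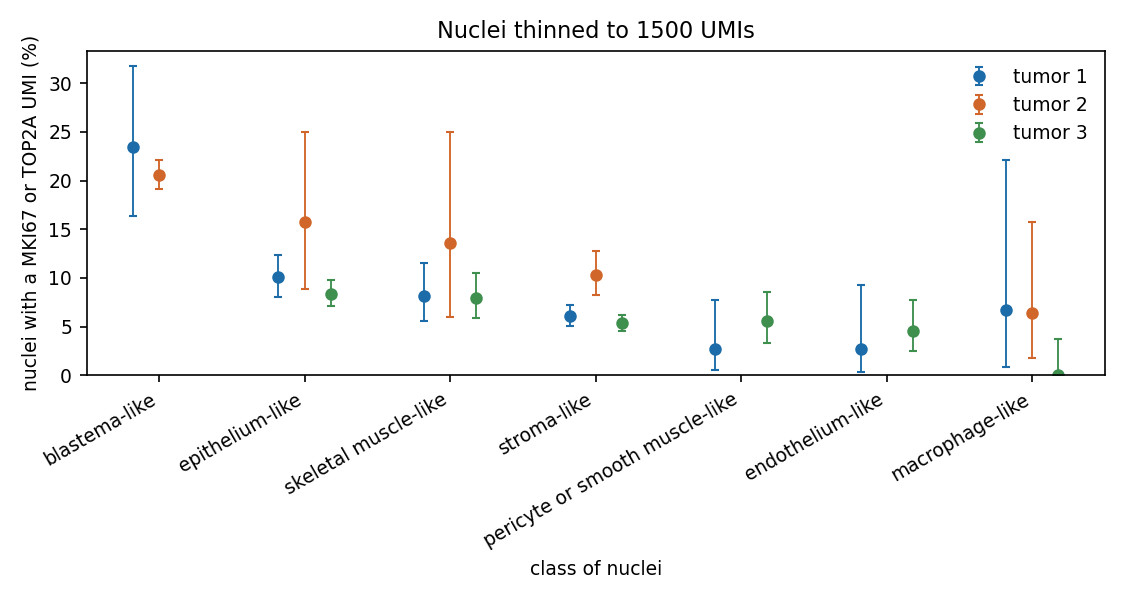
Share of nuclei (%) with a MKI67 or TOP2A UMI after thinning to 1500 UMIs, by class, with 1 point per tumor and exact binomial 95% confidence intervals. Blastema-like nuclei sit at 23.4% and 20.6%, above the epithelium-like and stroma-like points of the same tumors.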

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

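The earlier naming rule and the highest-blastema-score setting were chosen after the data were seen. No gene called in a class comparison was called in the opposite direction under any alternative run. Of the named called genes, 24 of 31 (stroma-like against epithelium-like), 30 of 30 (stroma-like against blastema-like) and 23 of 23 (epithelium-like against blastema-like) lost the call at least once. Scaling moved the median of all genes by under 0.1. Comparisons with blastema-like nuclei gave no value at Leiden resolution 0.5 or 2, at 1000 UMIs per nucleus or with clustering on a random part of the genes, where tumor 1 had no blastema-like sum, nor with a tumor left out. The self-test, run at a single depth, recovered 11% of 2-fold changes between stroma-like and epithelium-like sums, and with those sums thinned to equal totals the count of genes was 2587. Unless stated otherwise, the cause was not tested.

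Of 2600 genes between stroma-like and epithelium-like nuclei, the count was 4525 without the filter on low counts (more genes tested), 769 to 3241 with a tumor left out and 480 with no replicate block. It was 1259 with clustering on a random part of the genes, where fewer genes were tested (9408 against 14801). Of 1486 between stroma-like and blastema-like, it was 854 with DESeq2, 745 with relative log expression size factors, 565 with thinned sums and 0 by edgeR with no replicate block (1201 unadjusted). Of 460 between epithelium-like and blastema-like, it was 198 with DESeq2, 765 without the filter, 193 with thinned sums, 165 with clustering features included and 0 by edgeR with no replicate block (393 unadjusted).

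Of 18 list calls, 0 held with an estimated correlation, where the few residual degrees of freedom left camera little room to pass any list. Over all 54 tests fry gave 0 in one direction and 6 in either direction, of which 1 (imprinted genes, stroma-like against epithelium-like) was among the 18. The 5 between stroma-like and epithelium-like ranged from 3 to 8 with a tumor left out and fell to 1 with no replicate block. Between stroma-like and blastema-like, the imprinted call was lost with no replicate block, the TGF-beta and BMP call in 2 of 5 alternatives and the renal transcription factor call in 4 of 5, and between epithelium-like and blastema-like the last was lost in 2 of 5. The mean unnamed share fell to 2.35% at 1000 UMIs per nucleus. That setting removes shallow nuclei, and the others are also clustered and named anew. Tumor 1 then had 0% unnamed, although a cluster of 346 of its unnamed nuclei had a median of 4350 UMIs. The epithelium-like minus stroma-like share of nuclei with a MKI67 or TOP2A UMI (4.13 points) was 8.47 with no thinning, 1.51 at 1000 UMIs, 5.87 at 3000 UMIs, 6.51 with at least 2 G2/M genes and 1.38 with doublets kept. Blastema-like minus stroma-like (13.8) was 22.3 with no thinning, 21.5 with at least 2 G2/M genes and 8.68 with doublets kept, and blastema-like minus epithelium-like (9.10) was 13.9 with no thinning and 16.8 with at least 2 G2/M genes.

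Values that reversed were all of uncalled genes between stroma-like and epithelium-like nuclei. WT1 and GPC3 passed the threshold without tumor 2, and TOP2A did at 1000 UMIs per nucleus. With a tumor left out, WT1 ranged from -4.30 to 0.72, CTNNB1 from -0.28 to 0.22, MKI67 from -0.20 to 0.13 and GPC3 from -0.22 to 1.60. With no replicate block WT1 was 0.056. Without the filter CTNNB1 was 0.041 and MKI67 0.083, and MKI67 was 0.12 with doublets kept and 0.038 with the highest blastema score.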

Other observations

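The comparison of skeletal muscle-like with stroma-like nuclei, the splits of both sets of sums, both H19 tests and the ribosomal test below were chosen after the results were seen, as were the vascular and macrophage genes printed next. Levels here are plain CPM, as means ± SD over tumors, and were not tested between classes. Endothelium-like nuclei (tumors 1 and 3, n = 2) carried the Notch ligand DLL4 at 222 ± 161 CPM, against 5.35 CPM in the next named class, and EFNB2, an ephrin ligand of arterial endothelium, at 838 ± 124 against 115 CPM. The insulin receptor INSR was at 3901 ± 729 against 290 CPM. A cluster of 43 endothelium-like nuclei in tumor 3 was led by CCL21, STAB2 and RELN and also held FLT4 and PROX1, genes of lymphatic endothelium, among its top genes. Pericyte or smooth muscle-like nuclei (n = 2) carried PDGFRB at 989 ± 379 against 188 CPM and the transcription factor TBX2 at 204 ± 98.8 against 37.5 CPM. Macrophage-like nuclei (n = 3) carried PFKFB3, a glycolytic regulator, at 951 ± 208 against 138 CPM.

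Skeletal muscle-like nuclei, found in all 3 tumors, were set against stroma-like nuclei of the same tumors. RAPSN, which clusters receptors at the neuromuscular junction, was at 42.8 ± 12.9 against 0.403 ± 0.103 CPM (scaled as in the report; SD, n = 3; log2 fold change 6.66 ± 0.32, adjusted p = 0.00396). CDH15, the muscle cadherin, was at 102 ± 46.6 against 2.07 ± 1.12 CPM, the receptor FGFR4 at 56.7 ± 13.4 against 2.14 ± 0.967 CPM and the receptor MET at 192 ± 126 against 8.92 ± 6.36 CPM (5.72 ± 0.55, 4.60 ± 0.39 and 4.47 ± 0.19). Lower in skeletal muscle-like nuclei were TWIST1, at 8.47 ± 8.14 against 210 ± 164 CPM, and IGF1, at 11.5 ± 10.3 against 116 ± 101 CPM (-4.68 ± 0.31 and -3.30 ± 0.23, adjusted p = 0.00567 for both). In all, 362 of 12940 genes differed, 163 higher in skeletal muscle-like and 199 higher in stroma-like nuclei. The count was 785 with DESeq2, 1084 without tumor 2, 9 without tumor 3, 5 with no replicate block and 0 by edgeR without tumor 1 (1466 at an unadjusted p under 0.05), so it rests on tumors 1 and 3. Of the 18 lists, 10 passed at the preset correlation and 0 with an estimated one, which is limited by the few residual degrees of freedom. Extracellular matrix genes were lower, with 7 of 41 lower and 1 higher (20 and 4 adjusted over the list alone; median -0.83, camera, adjusted p = 1.07e-09, and adjusted p = 0.288 with an estimated correlation). Imprinted genes were higher, with 4 of 23 higher and 0 lower (7 and 0 adjusted over the list alone; median 0.56, adjusted p = 4.83e-06, and adjusted p = 0.288 with an estimated correlation), and CDKN1C was among them (1.35 ± 0.19, adjusted p = 0.0276). Neuronal adhesion and axon guidance genes were lower, with 3 of 30 lower and 2 higher (14 and 3 adjusted over the list alone; median -1.28, adjusted p = 0.000103, and adjusted p = 0.399 with an estimated correlation). Hypoxia and glycolysis genes were higher, with 3 of 22 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.50, adjusted p = 4.83e-06, and adjusted p = 0.399 with an estimated correlation). IGF signalling and retinoic acid genes passed as lower (medians -0.38 and -0.48, adjusted p = 0.00164 and 0.00730). The other 4 lost the call in some of 8 alternatives. HOX genes (lower, adjusted p = 0.0175) were at 0.0674 with no block, and renal transcription factors (lower, 0.0266) at 0.273 without tumor 1 and 0.0542 with no block. Notch genes (higher, 0.0305) were at 0.0904 without tumor 1 and 0.0658 without tumor 3. Cell-surface target genes tested as higher (0.0220) with a median of -0.0056, and were at 0.701 without tumor 2, 0.116 without tumor 3, 0.101 with no block and 0.202 with thinned sums.

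For the stroma-like and epithelium-like sums, 1 of the 10 splits of the 6 sums into 3 and 3, the real one, gave as many genes. The real value was 2600 and the highest other was 0 by edgeR (475 at an unadjusted p under 0.05, against 4937), and 10 splits are too few for a share under 0.05. For the skeletal muscle-like and stroma-like sums it was also 1 of 10, with 362 against a highest other of 0 by edgeR (715 unadjusted, against 2410), and again too few splits for a share under 0.05. The real split is 1 of 4 that part all 3 pairs, and the highest count among the other 3 was 0 in both comparisons. The remaining splits keep some pairs together. The classes were made from the expression of these same nuclei, so the real split was favoured from the start. These counts are therefore no support for the class differences.

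G2/M phase genes were lower in stroma-like than in blastema-like nuclei, with a median log2 fold change of -0.92. With the sums of each tumor thinned to the same total the median was -0.95. Random thinning keeps each gene's expected share of the total, so the median was bound to stay near its value. The test therefore cannot decide whether a difference in total count between the summed classes was a cause. Whether tumor 1's single cluster of 131 blastema-like nuclei, which carried GRHL2 at 273 CPM, is blastema in the tissue stays open, and no biological explanation was tested.

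In tumor 3, H19 was at 84.1 CPM in endothelium-like nuclei and at no more than 3.49 CPM in any other named class of at least 30 nuclei. Free RNA in the droplets is argued against for the class as a whole, since it would have brought H19 to the other classes as well. Low-UMI nuclei of tumor 3 outside the endothelium-like class were at 26.5 CPM (unnamed) and 42.1 CPM (a skeletal muscle-like cluster, from 3 UMIs), however, and free RNA stays open for low-UMI nuclei. An origin in a single endothelium-like cluster cannot be told apart from an origin in the class, as 2 of the 4 clusters were above 20 CPM: 1 of 170 nuclei held 219 of the 233 UMIs (130 CPM), and the other, of low UMI count, was at 46.0 CPM from only 4 UMIs, near the low-UMI skeletal muscle-like cluster. No biological explanation was tested.

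The unnamed clusters held 350, 1043 and 597 nuclei of low UMI count in tumors 1, 2 and 3 (median 841.5, 780 and 677 UMIs, against 3971.5, 7161 and 4817 in named nuclei). Whole nuclei that were only sampled less deeply are argued against, since the share of counts from ribosomal protein genes was 4.58, 7.09 and 5.74 times that of named nuclei. Cytoplasmic RNA in place of whole nuclei cannot be told apart from other sources: the nuclear RNA MALAT1 was at 0.824, 0.365 and 0.552 times its level in named nuclei, under 0.5 in 1 of the 3 tumors only. These nuclei were left out of every class sum, and no biological explanation was tested.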
